A study of Homo sapiens with 2 samples.

How the data were processed

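Spatial gene expression was measured on 2 Visium capture areas with the probe-based assay for formalin-fixed, paraffin-embedded human tissue. Each capture area, called an array here, held 4 scalp sections of 5 micrometres. The scarring alopecia array carried 2 sections of scarring alopecia beside 2 of healthy scalp, and the alopecia areata array carried 2 sections of alopecia areata beside 2 of healthy scalp. Staining with hematoxylin took 3 minutes and permeabilisation 40 minutes on both, per the labels' protocols. In this assay pairs of probes hybridise to fixed RNA, are ligated and are captured on barcoded spots, and each captured molecule is counted once through its unique molecular identifier (UMI).

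The deposited values are whole-number counts, the UMIs of each gene in each spot. Space Ranger 1.3.1 and Seurat, the latter with no version or role stated, and the genome build GRCh38 are named per the submitters' processing notes. Steps between the sequencing reads and the deposited counts beyond these names are not given in the sources used here. The counts had not been normalised, and all deposited spots entered the main results. Gene symbols and Ensembl identifiers were used as the files pair them. Of 17943 genes, 17876 matched a symbol or older symbol of a RefSeq gene table of assembly GRCh38.p14, which served to find chromosomes and older names only. XIST and the genes of chromosome Y, 10 genes in all, were left out of every step.

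The labels do not tie spots to sections, and spot positions were not used here, so each array pools diseased and healthy tissue of several people and counts as 1 sample with 1 library. No test between groups was made, no p-value or standard error is given, and no difference has a replicate check. All intervals are at the 95% level and cover counting error only. A ratio between the arrays therefore compares these libraries, not the diseases.

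Before the data were examined, the comparisons, 23 comparison lists of 258 genes, 12 marker lists of 106 entries, the rule for named genes and most of the alternatives were fixed. Of the comparison genes 246 were found in the counts, the other 12 not being analysed here, and of the marker entries 100 were used. The comparison lists covered T cells, cytotoxic lymphocytes, B and plasma cells, macrophages and monocytes, dendritic and Langerhans cells, mast cells, interferon gamma response, type I interferon response, MHC class I, MHC class II, JAK-STAT cytokine signalling, type 2 inflammation, lymphoid chemokines, extracellular matrix and fibrosis, epithelial-mesenchymal transition, bulge stem cells, dermal papilla and sheath, PPAR gamma and peroxisome, cholesterol synthesis, proliferation, keratinocyte stress, immediate early and heat shock genes, and haemoglobin. The marker lists covered hair shaft, inner root sheath, outer root sheath and basal keratinocytes, interfollicular epidermis, sebaceous gland, eccrine gland, melanocytes, dermal fibroblasts, endothelium, smooth muscle, adipose tissue and peripheral nerve. A list of 10 plasmacytoid dendritic cell genes was added later, after CLEC4C, SPIB, NIBAN3 and GZMB had been seen high in a region. None of its genes is in the cytotoxic list.

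UMIs were summed over all spots of an array and scaled to counts per 1000000 UMIs of the array (CPM). Log2 ratios are always the alopecia areata array over the scarring alopecia array, with 0.5 added to each count except for lists within a region. Those compare a list's summed UMIs per 1000000 UMIs of the region, with nothing added. Values of the arrays joined by "against" are in the same order. Intervals of a gene's ratio are exact conditional binomial (Clopper-Pearson) intervals, those of a CPM are exact Poisson intervals, and those of a share of spots are exact binomial (Clopper-Pearson) intervals. For a share of 0 spots the limit given is 3 spots of the total. Where an array had 0 UMIs of a gene, the ratio is given as a bound against 3 counts in that array. A list was summarised by the median log2 ratio of its members with at least 20 UMIs over both arrays, with an interval from 2000 binomial redraws of the counts. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is not a p-value.

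Genes were described by size, as those with at least 100 UMIs over both arrays and a ratio of 2-fold or more. The named genes are the members of the fixed lists as examples, the 12 largest ratios in each direction, the 3 largest in each direction within each region among genes with at least 50 UMIs there, and the 12 genes most enriched in spots with T cell UMIs in each array among genes with at least 50 UMIs in those spots. Genes of the second kind had to keep their direction in at least 3 of every 4 regions in which they had at least 10 UMIs, and this was read in the regions with at least 20 spots of both arrays. A gene with fewer UMIs in those regions passed by default. Class II HLA genes of very variable sequence were kept in their lists, but no level of them is printed, since what a probe reads can depend on inherited sequence. Immunoglobulin constant and variable genes, keratin-associated proteins, HBA1 and HBA2, and HSPA1A and HSPA1B have near-identical copies, so single values within those families are uncertain.

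Spots of both arrays were clustered together with scanpy 1.11.5 and igraph 0.11.9. Counts were scaled to 10000 per spot and log-transformed, the 2000 most variable genes were scaled with values limited to 10, and 20 principal components, 15 neighbours and Leiden resolution 0.5 were used. All genes of the comparison lists were left out of the clustering, so that list levels could be set between regions, but immunoglobulin genes outside the lists stayed in. Clusters are called regions and are described by their leading genes. A spot can hold several cells of different types, no doublet caller was run and no cell type makeup was estimated. Values were set between the arrays within a region only where each array had at least 20 spots in it.

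For shares of spots and for T cell spots, every spot was thinned at random to 1000 UMIs. Shallower spots were left out, 7 in the scarring alopecia array and 11 in the alopecia areata array. A T cell spot had at least 1 UMI of the T cell list after thinning. Its observed UMIs of other lists and genes, at full depth, were divided by those expected from the spots without such a UMI in the same region and array at the same total, with intervals from 2000 Poisson redraws.

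Alternatives were edgeR 4.0.16 TMM scaling, scaling without genes over 1% of the UMIs, equal weight per spot, spots with at least 500 UMIs, other UMI minimums, region-standardised ratios, other resolutions and gene sets for the clustering, scaling within each array, other T cell spot definitions and other thinning depths. Added after seeing the data were ratios standardised by the leading marker list of each spot, ratios without region 5 or another single region, ratios without regions 8 and 10, all spots thinned to 1000 UMIs, and the plasmacytoid list without TCF4 for GZMB. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used.

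The steps were tested on simulated data. Among the 12744 genes compared between the arrays, 67 genes planted at 3-fold and 67 at 8-fold were all found at 2-fold or more (100%), 66 planted at 1.5-fold gave 0%, and unchanged genes gave 0%. The intervals held the planted ratio for 90.9%, 95.5%, 92.5% and 95.25% of genes planted at 1.5-fold, 3-fold, 8-fold and unchanged. For the list shift, 20 of 20 lists of 15 genes planted at -0.50 lay below percentile 5, with a mean median of -0.49, and 5 of 100 unchanged lists did. In the simulations of genes and lists, counts were Poisson draws around a mean shared by both arrays, and all genes not planted were unchanged. On the real arrays 938 of 12744 genes were at least 2-fold apart, so these rates need not carry over. For T cell spots, 200 of 600 genes planted at 1.00 on the log2 scale had a median of 0.99 and 97.5% of intervals held it. The others had a median of 0.00. In that simulation spots were picked at random within simulated regions and counts were Poisson draws. The choice of spots by thinned T cell UMIs was therefore not tested.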

Results

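The data describe scalp tissue in autoimmune hair loss, as UMI counts over spots of a tissue array. Scarring alopecia destroys the follicle, whereas in alopecia areata the follicle persists and can regrow hair, and the design sets each disease beside healthy scalp on an array of its own. The scarring alopecia array gave 1420 spots and 16821285 UMIs, with a median of 8199.5 UMIs and 4016.5 genes per spot. The alopecia areata array gave 1211 spots and 11554581 UMIs, with a median of 6330.0 UMIs and 3435 genes per spot. Genes with at least 1 UMI numbered 17363 and 17419. Each array is 1 library that mixes 2 diseased and 2 healthy sections, and the labels do not say which spot lies on which section, so every comparison is between arrays or between parts of an array, without replicates.

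The comparison of all genes asked how the transcript content of the arrays differed. Hair-forming tissue was abundant on the alopecia areata array and nearly missing from the scarring alopecia array. The 11 measured hair shaft genes, which encode hair keratins, summed to 18335 CPM on the alopecia areata array and 18.3 CPM on the scarring alopecia array, and the 9 inner root sheath genes to 17466 and 7.79 CPM. Markers of cornified surface epidermis went the other way, with 9 of 11 interfollicular epidermis genes lower in the alopecia areata array and sums of 5354 against 18824 CPM. Adipose genes were higher on the alopecia areata array in 7 of 7 cases, at 1325 against 84.2 CPM. The labels do not give the tissue make-up of the sections, so these directions describe the arrays. The scarring alopecia array also carried 2 sections of healthy scalp, so the near absence of hair shaft genes covers healthy as well as diseased tissue there. That absence cannot be assigned to scarring alopecia alone.

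Of 12744 genes with at least 100 UMIs, 451 were at least 2-fold higher in the alopecia areata array and 487 at least 2-fold higher in the scarring alopecia array. The 12 largest ratios toward the alopecia areata array were all of hair keratins, inner root sheath keratins or keratin-associated proteins, the matrix proteins in which hair keratins are embedded. KRT85 (ENSG00000135443) had 1 UMI on the scarring alopecia array and 18821 on the alopecia areata array, a log2 ratio of 14.16 (interval 12.26 to 20.05). KRT83 had 7 and 37169 UMIs, with a log2 ratio of 12.82 (11.87 to 14.23). KRT25 and KRT71 of the inner root sheath had log2 ratios of 12.75 (11.95 to 13.88) and 12.71 (11.70 to 14.27). KRTAP1-1 was not detected on the scarring alopecia array, where 3 counts stand for 0.178 CPM, and at 316 CPM it was at least 1774-fold higher on the alopecia areata array. KRTAP2-4 was likewise at least 1579-fold higher. KRT35, KRTAP3-1, KRTAP1-5, KRTAP3-3, KRTAP2-2 and KRTAP26-1 completed the set, each with 1 or 2 UMIs on the scarring alopecia array.

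Toward the scarring alopecia array, the largest ratio was that of FLG (ENSG00000143631), the filaggrin precursor of the cornified layer, at 6.58 against 808 CPM and a log2 ratio of -6.93 (-7.29 to -6.62). KRT1 (-6.02, -6.19 to -5.87) and KRT2 (-5.27, -5.54 to -5.02), keratins of suprabasal epidermis, followed the same direction, as did the cornified envelope genes LCE5A (-5.46) and SPRR2G (-5.24) and the secreted epidermal protein SLURP2 (-5.87). IGFL1 (-6.52), SERPINB12 (-4.95), WFDC12 (-4.75), AL603764.2 (-4.76) and the collagenase gene MMP13 (-4.82, from 184 and 4 UMIs) were also among the 12. The remaining gene was a class II HLA gene whose level is not given.

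Other tissue markers moved in several directions. Outer root sheath and basal keratinocyte genes split, with a median log2 ratio of 0.03 and 4 of 8 genes higher in the alopecia areata array, among them KRT75 at 670 against 17.7 CPM (5.24, 5.07 to 5.41). Sebaceous genes were lower there in 12 of 13 cases (median -0.49) and melanocyte genes higher in 4 of 5 (median 1.78, 274 against 83.7 CPM). Eccrine gland genes were higher in 8 of 10 (median 2.65), led by DCD, which encodes the sweat peptide dermcidin, at 344 against 0.476 CPM. Dermal fibroblast genes (median -0.43), endothelial genes (-0.24, lower in 6 of 6), smooth muscle genes (-0.54) and peripheral nerve genes (-0.37) had medians below 0, though the nerve genes were level as a sum, at 104.6 against 105.7 CPM. Without regions 8 and 10, the hair-forming and adipose-rich parts of the alopecia areata array described with the regions, 222 genes were at least 2-fold higher in the alopecia areata array in place of 451.

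The comparison of gene lists asked which immune, interferon, matrix and follicle programmes differed between the arrays. Over whole arrays, immune and matrix transcripts were lower on the alopecia areata array and higher on the scarring alopecia array, and proliferation and dermal papilla genes were higher on the alopecia areata array. Of 23 lists, 19 had a median below 0, 15 lay below percentile 5 of matched random lists and 3 lay above percentile 95. Without region 5 of the scarring alopecia array 11 lists had a median below 0, but leaving out a part of 1 array is one-sided, and leaving out region 7 instead moved the T cell median to -1.30.

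T cell genes had a median log2 ratio of -0.81 (-0.89 to -0.70, percentile 0), with 17 of 19 lower in the alopecia areata array. CD3E, a chain of the T cell receptor complex, was at 12.5 against 25.4 CPM (-1.02, -1.31 to -0.75), and TRAC was at 52.6 against 90.8 CPM. The exceptions were CTLA4 (0.40, 0.07 to 0.71) and CD6 (0.11, -0.15 to 0.37). The T cell median turned to 0.43 without region 5 and to 1.37 when spots were set against spots of the same region. Here and below, values set region against region cover only regions 1 and 4, the regions with at least 20 spots of both arrays. Those regions held 33 and 123 of the 1211 alopecia areata array spots, and their membership was unstable under other clusterings. B and plasma cell genes were the lowest list, at -1.51 (-1.92 to -1.26, percentile 0), with 13 of 15 lower. JCHAIN, the joining chain of secreted antibodies, had a log2 ratio of -2.05 (-2.21 to -1.88) and IGHG1 -2.26 (-2.31 to -2.22), while IGHA1 (0.49) and IGHG4 were higher in the alopecia areata array. Without region 5 this median was 0.37, and set region against region it was -0.22.

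Cytotoxic lymphocyte genes differed less, with a median of -0.24 (-0.49 to 0.02, percentile 14.2) and members on both sides. CD8A (0.68, 0.03 to 1.33) and NKG7 (0.62, 0.06 to 1.18) were higher in the alopecia areata array, from 44 and 58 UMIs there. GZMB, which encodes granzyme B, was lower by a wide margin, at 1.90 against 14.0 CPM (-2.85, -3.58 to -2.25). The cytotoxic median was 0.44 without region 5 and, on the 5 of 13 genes with enough UMIs, 1.33 set region against region. Macrophage and monocyte genes had a median of -0.19 (-0.31 to -0.11, percentile 3.12), with CD14 (0.65) and FCGR3A (0.72) higher and CD68 (-0.91) lower, and their median also turned, to 0.41 without region 5. Dendritic and Langerhans cell genes were lower at -0.94 (-1.06 to -0.80, percentile 0), led by CCR7, the receptor that guides cells to lymph nodes (-2.51), and CD1C (-1.88), whereas the Langerhans cell gene CD207 was level (0.12, -0.03 to 0.28). That median was -0.27 without region 5 and 0.83 set region against region. Mast cell genes split, with a median of 0.07 (-0.07 to 0.21, percentile 69.1) and sums of 497 against 839 CPM. KIT (0.38) and HDC (0.22) were higher and the tryptase gene TPSB2 lower (-1.50). The mast cell median was 0.56 without region 5, 0.82 set region against region and -0.36 without region 7.

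Interferon-induced genes were lower in the alopecia areata array. All 14 type I interferon response genes had ratios below 0, with a median of -0.66 (-0.82 to -0.51, percentile 0), including the antiviral genes MX1 (-1.40), OAS1 (-1.39) and IFI27 (-1.27). IFI6 and IFIT1 were level at -0.02 each. The type I median was -0.28 without region 5 and -0.08 set region against region. It was -0.32 with each spot weighted equally and -0.37 with all spots thinned to 1000 UMIs (11 of 14 genes). Interferon gamma response genes had a median of -0.56 (-0.62 to -0.28, percentile 0.01), with 13 of 15 lower, among them UBD (-1.69), IDO1 (-1.18) and CXCL9, a chemokine induced by interferon gamma (-0.57, -1.08 to -0.09). This median was 0.04 without region 5 and 0.62 set region against region. MHC class I genes had a median of -0.44 (percentile 0.16, 7 of 8 lower, B2M at -0.50), -0.13 without region 5 and 0.72 set region against region. MHC class II genes had a median of -0.73 (-0.79 to -0.66, percentile 0, 10 of 10 lower), with CD74 at -0.53, HLA-DMB at -0.81 and the class II transactivator CIITA at -0.69, and the median turned to 0.18 without region 5 and to 1.08 set region against region. Some of these 10 are HLA genes of very variable sequence, whose probes can depend on inherited sequence, so the count may not be of expression alone.

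Signalling lists followed. All 13 JAK-STAT cytokine genes were lower in the alopecia areata array (median -0.41, percentile 0.21), with IL15 at -1.22, the shared receptor chain IL2RG at -1.06 and JAK3 at -0.20, and the median was -0.03 without region 5 and 0.64 set region against region. All 6 lymphoid chemokine genes were lower (median -0.65, percentile 0.16), among them CCL19 (-0.94) and CXCL13 (-0.49), though the median was 0.31 without region 5 and 1.10 set region against region. Type 2 inflammation genes split. CCL17 (-2.63) and CCL22 (-1.93) were lower, CCL18 (1.41, 1.28 to 1.55) and CCL26 (2.03) were higher, and the median was -0.31 (-0.58 to -0.22, percentile 4.37). The sum was level at 238 against 235 CPM, and the median was 0.029 without regions 8 and 10 and, on 5 of 7 genes, -0.016 with all spots thinned.

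Matrix genes were lower in the alopecia areata array, at a median of -0.69 (-0.80 to -0.67, percentile 0) with 18 of 20 lower. COL1A1 was at 1513 against 4006 CPM (-1.41), COL3A1 at -1.19 and CTHRC1, a gene of collagen-producing fibroblasts, at -1.95. COL11A1 (1.56) and TGFB2 (0.71) were higher. The matrix median was -0.18 without region 5 and 1.05 set region against region. Epithelial-mesenchymal transition genes had a median of -0.47 (percentile 0.900, 5 of 7 lower), with TWIST2 at -1.09 and VIM at -0.47, and medians of -0.008 without region 5 and 0.62 set region against region. Keratinocyte stress genes had a median of -0.51 (-0.57 to -0.46, 6 of 8 lower), with SPRR1B at -1.06 and S100A8 at 0.18. Their median was 0.88 set region against region and -0.006 standardised by leading marker list. It depended on single regions, at 0.105 without region 3 and -1.43 without region 4. Immediate early genes such as FOSB (-0.76) and FOS (-0.34) were lower while the heat shock genes HSPA1A (1.39) and HSPA1B (1.11) were higher, for a list median of -0.28 (percentile 3.38), and -0.90 set region against region.

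Dermal papilla and proliferation genes went the other way. Dermal papilla and sheath genes, of the mesenchyme that instructs hair growth, had a median of 1.36 (1.12 to 1.59, percentile 100) with 8 of 9 higher in the alopecia areata array, including HHIP (4.14, 3.06 to 5.73), WIF1 (3.15, 1.90 to 4.98) and BMP4 (1.36, 1.09 to 1.63). CORIN was the exception at -1.67, and because it was the most abundant member on the scarring alopecia array the summed CPM was level, at 101 against 96.9. All 11 proliferation genes were higher, with a median of 0.75 (0.65 to 0.83, percentile 100), among them RRM2 (1.06) and TOP2A (0.75, 0.60 to 0.90). Without regions 8 and 10 the dermal papilla median was 0.58 and the proliferation median 0.28. Set region against region they were 0.73 (4 of 9 genes) and 0.21, where the median of all genes was 0.16. As sums, proliferation genes were level in region 1 (-0.05, -0.33 to 0.22) and higher in region 4 (0.62, 0.48 to 0.76). Bulge stem cell genes were level as a list (-0.01, -0.04 to 0.04, percentile 43.4), with KRT15 at -0.01, although LHX2 (3.50) and LGR5 (3.45, 86.6 against 7.91 CPM) were much higher in the alopecia areata array. PPAR gamma and peroxisome genes (-0.09, percentile 20.3) and cholesterol synthesis genes (-0.11, percentile 13.4) stood close to random lists. The cholesterol median depended on single regions, at 0.56 without region 1, -0.78 without region 7 and -0.73 set region against region. The PPAR gamma and peroxisome median did so too, at 0.38 without region 1 and -0.54 without region 7. The 2 haemoglobin genes were higher, with a median of 0.98 (percentile 97.7).

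**Figure D1:**
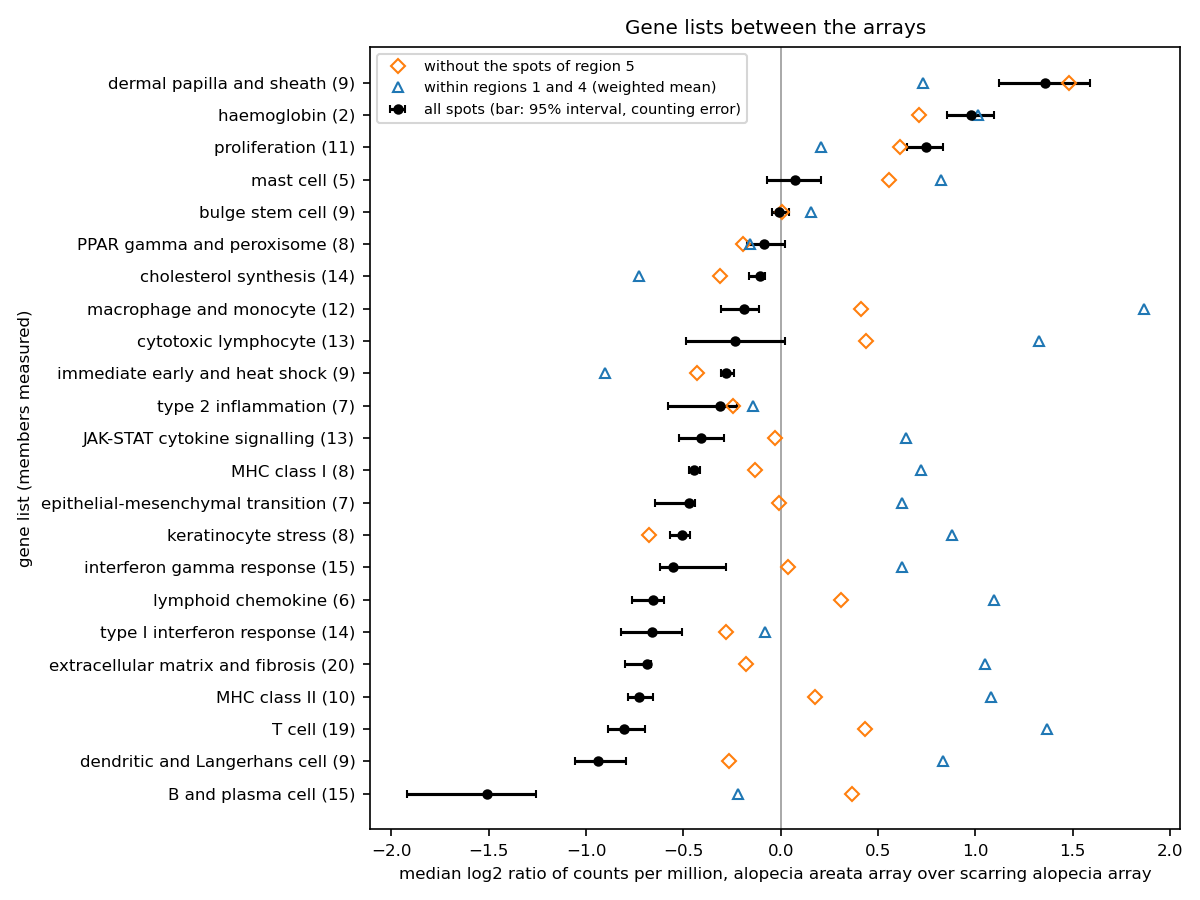
Median log2 ratio of CPM, alopecia areata array over scarring alopecia array, for 23 gene lists (vertical axis, with the number of measured members), each library being 1 array. Black points and bars are all spots with 95% counting intervals, orange diamonds leave out region 5 and blue triangles are weighted means within regions 1 and 4; 19 black points lie left of 0, and the T cell list moves from -0.81 to 0.43 and 1.37.

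The comparison of regions asked which tissue parts each array contained. Clustering gave 12 regions, of which 10 lay almost wholly on 1 array. On the scarring alopecia array alone were region 5 (352 spots, 24.8%, 22.6 to 27.1%), whose leading genes included the immunoglobulin segment IGHJ6, NIBAN3, CLEC4C and SPIB with abundant complement (C3, C1S) and collagen VI transcripts, and region 3 (353 spots, 24.9%), led by TCN1, DEFB4A and the epidermal KRT1 and FLG. Region 2 (272 spots, 19.2%) was led by MSMB with abundant PTGDS and DCN, and region 6 (61 spots, 4.30%) by SLURP1, KRT2 and LOR. Each of these 4 regions had 0 of 1211 spots on the alopecia areata array, which allows a share of up to 0.248%.

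On the alopecia areata array lay region 8 (246 spots, 20.3%, 18.1 to 22.7%) of hair keratins such as KRT33B and KRT34, region 9 (288 spots, 23.8%) of sweat gland, fibroblast and fat genes such as DCD, CFD and PLIN1, and region 10 (165 spots, 13.6%), led by EDN3, ADIPOQ and MYCN with abundant histone and KRT35 transcripts. Region 11 (57 spots, 4.71%) was led by SHISA2 and NELL2 with abundant KRT14 and KRT5, and region 12 (28 spots, 2.31%) by PIP, DCD and AQP5, with 7 eccrine markers among its 10 leading genes. These 5 regions had 0 of 1420 spots on the scarring alopecia array, which allows up to 0.211%. Region 7, led by SAA1 and PM20D1 with abundant lipid genes such as FASN and DGAT2, had 271 spots (22.4%) there against 2 (0.141%). Sebaceous gland genes summed to 14852 CPM in region 7, second to 22071 CPM in region 1 and above 6894 CPM in region 4.

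Only 2 regions had at least 20 spots of both arrays. Region 1 held 270 spots of the scarring alopecia array (19.0%) and 33 of the alopecia areata array (2.73%), and joined sebaceous genes (AWAT2, FADS2, HSD3B1) with smooth muscle genes (DES, CNN1, ACTG2). Region 4 held 110 spots (7.75%) and 123 spots (10.2%), with SPRR4, KLK12 and CST6, genes of differentiating keratinocytes. With 1 library per array, a region held by that array may be the library rather than a tissue type. Regions 1 and 7 were both rich in sebaceous genes and lay mostly on different arrays, so like tissue may be divided between them. Membership of the shared regions was also unstable, since leaving out the 3 spots under 500 UMIs moved the alopecia areata share of region 1 to 0.165% and of region 4 to 6.11%.

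The comparison of lists by region asked where each programme sat and how like tissue compared between arrays. Immune transcripts of the scarring alopecia array were concentrated in region 5, where T cell genes reached 1707 CPM (1664 to 1750), 7.35-fold the rest of that array. B and plasma cell genes reached 19672 CPM there, 19.1-fold the rest, with the reservation that immunoglobulin genes outside the list helped to define the region. Cytotoxic genes were 5.04-fold, lymphoid chemokine genes 4.86-fold, MHC class II genes 4.48-fold, macrophage genes 4.46-fold, mast cell genes 4.21-fold and matrix genes 4.16-fold the rest of the array. Interferon gamma and type I interferon response genes were higher by less, 1.99-fold and 1.76-fold, and cholesterol synthesis genes were at 0.264 of the rest.

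On the alopecia areata array T cell genes and B and plasma cell genes were highest in different regions. Region 9 carried B and plasma cell genes at 13043 CPM (17.1-fold the rest of its array), type 2 inflammation genes at 1532 CPM (12.3-fold) and matrix genes at 18743 CPM (2.87-fold). T cell genes were highest in region 7, at 538 CPM (514 to 563) or 2.25-fold the rest. Macrophage genes (2.65-fold), cytotoxic genes (2.49-fold) and cholesterol synthesis genes (3.32-fold) were also above the rest there. Region 9 was level with region 7 in macrophage genes (1352 and 1349 CPM) and cytotoxic genes (104.3 and 104.2 CPM). It was above region 7 in lymphoid chemokine genes (1155 and 987 CPM), MHC class II genes (3564 and 3313 CPM) and mast cell genes (831 and 703 CPM). T cell genes were lower in region 9, at 378 CPM or 1.16-fold the rest, as were JAK-STAT genes (697 and 824 CPM). Proliferation genes were concentrated in region 10 (1755 CPM, 4.18-fold), where dermal papilla genes also stood highest on that array (2.19-fold), and bulge stem cell genes in region 11 (4901 CPM, 3.53-fold). Keratinocyte stress genes were 7.50-fold the rest in region 4 of the alopecia areata array and 3.83-fold in region 3 of the scarring alopecia array.

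**Figure D2:**
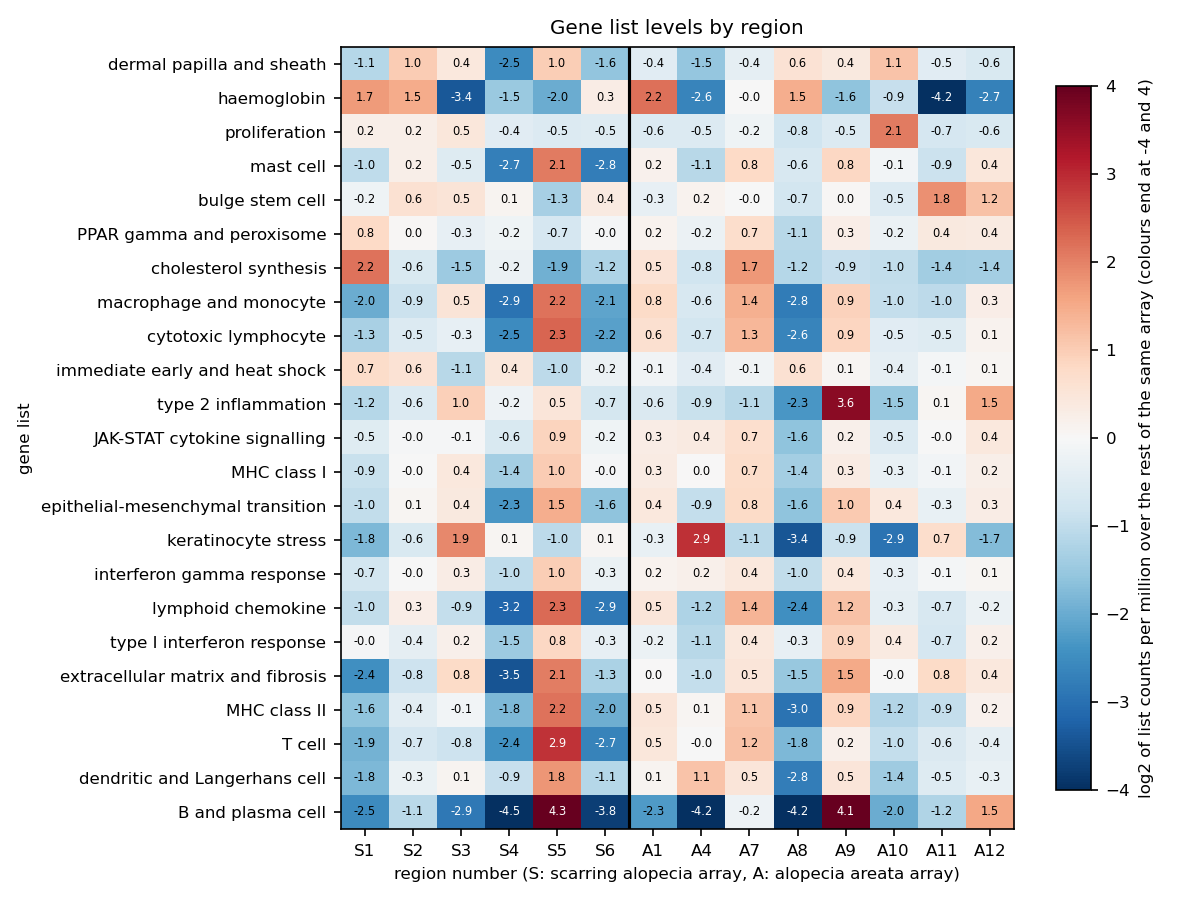
Heat map of the log2 ratio of each gene list's CPM in a region over the rest of the same array, with lists as rows and regions as columns (S, scarring alopecia array; A, alopecia areata array; regions with at least 20 spots on that array; colours end at -4 and 4). T cell genes peak in S5 at 2.9, and B and plasma cell genes in S5 at 4.3 and A9 at 4.1.

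Within the shared regions the direction of most immune lists was opposite to that of the whole arrays. T cell genes were higher in the alopecia areata array in region 1 (450 against 184 CPM, log2 ratio 1.29, 1.02 to 1.55) and in region 4 (329 against 119 CPM, 1.46, 1.28 to 1.65). Macrophage genes (log2 ratios of 2.01 and 1.80), cytotoxic genes (93.1 against 37.8 CPM and 40.1 against 15.8 CPM), MHC class II genes (2896 against 1323 CPM and 2184 against 1089 CPM), matrix genes (1.02 and 1.32), keratinocyte stress genes (1.01 and 1.42) and MHC class I genes (0.56 and 0.76) were also higher there in regions 1 and 4. Interferon gamma response genes were higher at 0.41 (0.17 to 0.64) and 0.73 (0.60 to 0.85), as were 16 of the 23 lists in each region. Lower in the alopecia areata array in both were B and plasma cell genes (-1.58 and -1.22). So were type I interferon genes (251 against 503 CPM and 154 against 209.5 CPM). Cholesterol synthesis genes (-0.93 and -0.66) and immediate early and heat shock genes (-0.70 and -0.78) were lower in both too. These ratios compare summed CPM, to which abundant members add most. Medians over members in both regions together were smaller in size for B and plasma cell genes (-0.22, 10 of 15 genes) and type I interferon genes (-0.08). Haemoglobin differed at 1.97 in region 1 and was level at -0.07 in region 4.

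The largest single ratios within these regions were hair keratins on the alopecia areata array. In region 1, KRT83 had 0 and 106 UMIs, KRT71 0 and 98 and KRT85 0 and 80. In region 4, KRT85 had 0 and 242 UMIs, KRT35 0 and 180 and KRT83 1 and 388. In the other direction the largest ratios were of class II HLA genes, whose levels are not given. The ratio standardised over both regions had a median of 0.16 over all genes, so values near that size are common to most genes. The regions rest on 33 and 123 spots of the alopecia areata array and hold hair keratin transcripts almost only on that array. Tissue within them may therefore not have been fully alike, although hair shaft genes also reached 5044 CPM in region 12 and 1871 CPM in region 7. Region 7, also rich in sebaceous genes, is left out.

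The comparison of T cell spots asked which programmes shared spots with T cell transcripts in each array, with region held fixed. At a depth of 1000 UMIs, 33.5% of scarring alopecia array spots (474 of 1413, 31.1 to 36.1%) and 26.25% of alopecia areata array spots (315 of 1200, 23.8 to 28.8%) had a T cell UMI. Without thinning the shares were 83.6% and 70.9%. Within the scarring alopecia array the share ran from 4.63% in region 4 to 69.4% in region 5, at median depths of 26392 and 8219 UMIs, and within the alopecia areata array from 10.7% in region 12 to 36.5% in region 7. Shares for B and plasma cell genes were 65.6% and 46.0%, for cytotoxic genes 8.35% and 7.17%, for type 2 inflammation genes 22.8% and 27.3%, and for proliferation genes 25.9% and 37.0%, in the scarring alopecia and alopecia areata arrays.

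T cell spots carried more cytotoxic, antigen-presentation and interferon gamma response transcripts than other spots of the same region on both arrays. Cytotoxic genes were higher by 0.83 on the log2 scale (0.60 to 1.09) on the scarring alopecia array and by 1.01 (0.79 to 1.24) on the alopecia areata array, a 1.78-fold and 2.01-fold level. MHC class II genes stood at 0.44 (0.41 to 0.47) and 0.67 (0.63 to 0.70), MHC class I genes at 0.28 and 0.45, interferon gamma response genes at 0.39 (0.31 to 0.48) and 0.35 (0.27 to 0.43), and type I interferon genes at 0.15 (0.07 to 0.25) and 0.25 (0.14 to 0.36). With spots defined on all counts the type I value on the alopecia areata array was -0.003. Dendritic and Langerhans cell genes (0.55 and 0.35), JAK-STAT genes (0.26 and 0.24) and type 2 inflammation genes (0.48 and 0.20) were likewise above 0 on both.

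Several lists were raised more on the alopecia areata array, though the difference was not tested. The gap can depend on how a T cell spot is defined. After thinning 939 spots of the scarring alopecia array and 885 of the alopecia areata array had no T cell UMI. On all counts 227 and 345 had none, so many comparison spots carried T cell transcripts, and on the scarring alopecia array more so. Macrophage genes stood at 0.26 (0.21 to 0.32) on the scarring alopecia array and 0.77 (0.71 to 0.84) on the alopecia areata array, lymphoid chemokine genes at 0.19 and 0.64, epithelial-mesenchymal transition genes at 0.25 and 0.53, and mast cell genes at 0.05 (-0.01 to 0.11) and 0.59 (0.51 to 0.67). Cholesterol synthesis genes were lower in T cell spots on both arrays, at -0.22 (-0.25 to -0.18) and -0.70 (-0.73 to -0.67), as were PPAR gamma and peroxisome genes at -0.10 and -0.14. Proliferation (0.05 and 0.05) and dermal papilla genes (0.04 and 0.14) were level within their intervals. Of 22 lists, 11 had intervals above 0 on both arrays, 2 below 0 on both and 4 on opposite sides.

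The genes most raised in T cell spots of the scarring alopecia array, among 11060 with enough UMIs, were led by immune receptor and lymphocyte genes. IGKV5-2 (2.69, 1.88 to 3.86) and TRAV8-6 (2.28) are receptor segments, CCR7 stood at 1.80 (1.22 to 2.59), the interferon-induced chemokine CXCL9 at 1.80 (0.97 to 2.92), CD7 at 1.49 and GZMA at 1.49 (0.80 to 2.36). FAM24B, TRAJ41, TRAJ35, SLC4A8, ADAMDEC1 and DCLRE1B made up the 12, from 1.75 to 1.41. On the alopecia areata array, among 9562 genes, the activation marker CD69 led at 2.15 (1.62 to 2.77), followed by IGHG3 (2.03) and TRAJ34 (1.86). The adhesion molecules of activated vessels SELP (1.59) and SELE (1.13), the T cell kinase gene ZAP70 (1.56), GBP5 (1.27), the chemokines CXCL13 (1.23, 0.89 to 1.58) and CCL5 (1.18), TAGAP, SEPTIN1 and TRAJ16 completed the set. Without standardising by region the cytotoxic value was 2.03 on the scarring alopecia array, and the MHC class II values were 1.71 and 1.05.

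**Figure D3:**
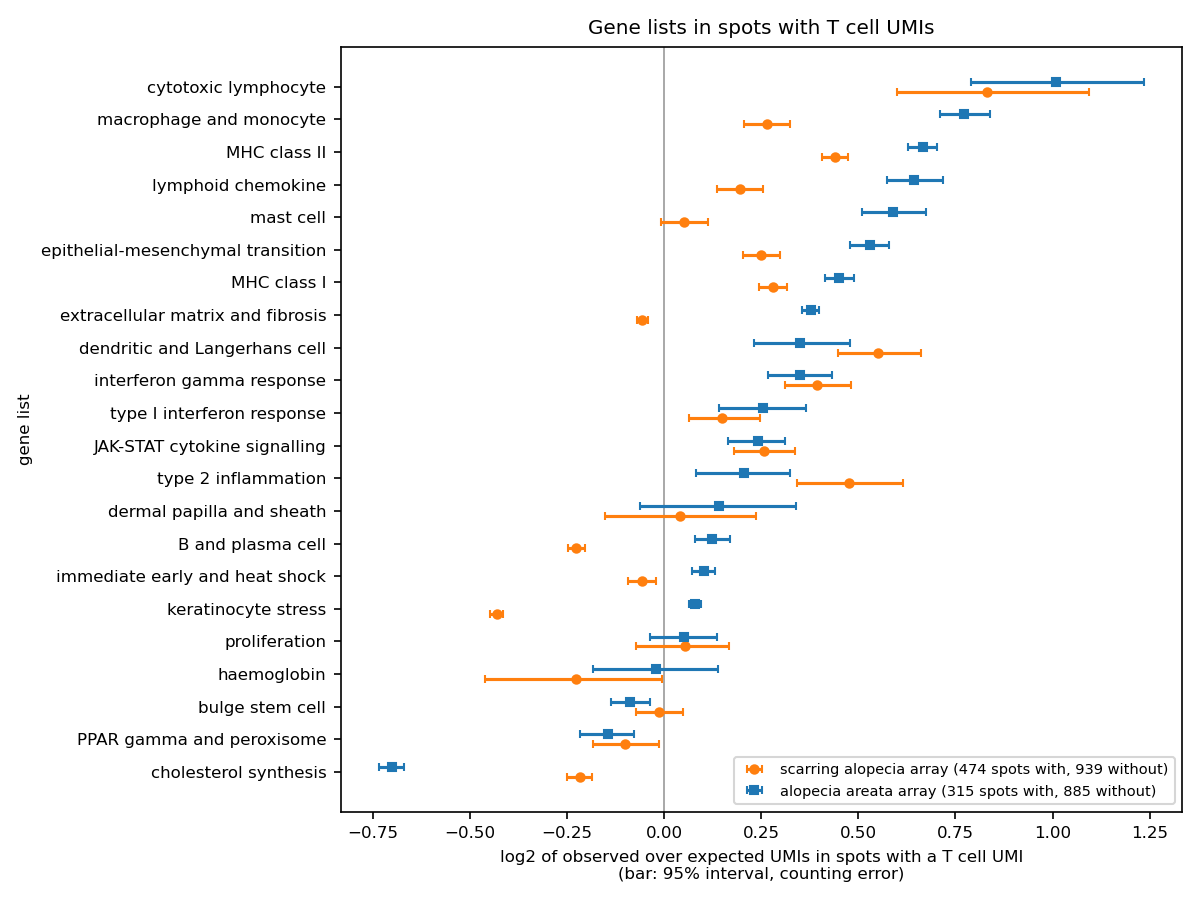
Log2 of observed over expected UMIs of each gene list (vertical axis) in spots with a T cell UMI, against spots of the same region and array without one, for the scarring alopecia array (orange circles, 474 and 939 spots) and the alopecia areata array (blue squares, 315 and 885 spots), with 95% counting intervals as bars. Cytotoxic genes lie highest on both arrays, at 0.83 and 1.01, and cholesterol synthesis genes are the lowest on the alopecia areata array at -0.70.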

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

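In T cell spots, set against spots of the same region without a T cell UMI, 4 lists lay above the expected level on the alopecia areata array and below it on the scarring alopecia array. The difference between the arrays was not tested, since each array is 1 library. B and plasma cell genes stood at -0.23 (-0.25 to -0.20) on the scarring alopecia array and 0.12 (0.08 to 0.17) on the alopecia areata array. Extracellular matrix and fibrosis genes stood at -0.056 (-0.070 to -0.041) and 0.38 (0.36 to 0.40). Keratinocyte stress genes stood at -0.43 (-0.45 to -0.41) and 0.079 (0.065 to 0.094). Immediate early and heat shock genes stood at -0.057 (-0.092 to -0.022) and 0.10 (0.07 to 0.13). No biological explanation was tested for these opposite directions, and each of the 4 lost these directions under at least 1 other definition of a T cell spot. With spots defined on all counts matrix genes were at 0.58 and 0.48 and keratinocyte stress genes at 0.28 and 0.31, above the expected level on both arrays, and B and plasma cell genes at 0.056 and -0.093, with the directions exchanged. At a thinning depth of 500 UMIs B and plasma cell genes were at 0.70 and 0.43, and without standardising by region immediate early and heat shock genes were at -0.51 and -0.047.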

How the results depend on the processing

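Depth limits rare transcripts most, since a gene with 0 UMIs could lie at up to 0.178 CPM on the scarring alopecia array and 0.260 CPM on the alopecia areata array. The alternatives without region 5, without regions 8 and 10, standardised by leading marker list and with all spots thinned to 1000 UMIs were chosen after seeing the data, the others beforehand. Of the list medians under all alternatives, 123 stayed within their counting interval, 84 moved beyond it with no called change of sign and 23 were called as changed in sign. A change was called only for lists whose counting interval excluded 0. Sign changes of other lists, such as cytotoxic genes, are not in that count. Scaling with edgeR TMM factors moved 2 of 23 list medians and left 21 within their intervals, and spots with at least 500 UMIs and members with at least 100 UMIs left all 23. Scaling without genes over 1% of the UMIs could move nothing, because no gene passed 1%. The shares of spots with a list UMI moved in all 138 cases, as thinning and the UMI minimum set them. Of the values in T cell spots 50 kept within their interval, 113 moved and 13 were called as changed in sign. With genes scaled within each array no region was shared, so list levels within regions could not be obtained. Unless stated otherwise the cause was not tested for any value given here. No paired analysis was possible because each group is 1 library.

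Minimums change which genes are counted by construction. With at least 20 UMIs, 768 genes were 2-fold or more higher in the alopecia areata array and 743 in the scarring alopecia array, 1511 together, and with at least 500 UMIs 231 and 247, 478 together. Region-standardised ratios gave 286 genes higher in the scarring alopecia array. Without regions 8 and 10 the count higher in the alopecia areata array was 222 and the total 562.

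Region-standardised list medians were 1.37 for T cell, 1.33 for cytotoxic (5 of 13 genes), -0.22 for B and plasma cell, 1.86 for macrophage, 0.83 for dendritic and Langerhans cell, 0.62 for interferon gamma, 0.72 for MHC class I, 1.08 for MHC class II, 0.64 for JAK-STAT, 1.10 for lymphoid chemokine, 1.05 for matrix, 0.62 for epithelial-mesenchymal transition, 0.73 for dermal papilla (4 of 9 genes), -0.73 for cholesterol synthesis, 0.88 for keratinocyte stress and -0.90 for immediate early genes, with 6 of 23 lists below 0. Without region 5 they were 0.43 for T cell, 0.44 for cytotoxic, 0.37 for B and plasma cell, 0.41 for macrophage, 0.035 for interferon gamma, 0.18 for MHC class II, 0.31 for lymphoid chemokine and -0.18 for matrix genes, with 11 lists below 0. Without regions 8 and 10 they were -0.40 for T cell, 0.16 for cytotoxic, -1.18 for B and plasma cell, 0.22 for macrophage, -0.17 for interferon gamma, 0.029 for type 2 inflammation, -0.80 for matrix, 0.58 for dermal papilla, 0.060 for cholesterol synthesis and 0.018 for keratinocyte stress genes, with 12 lists below 0. Standardised by leading marker list they were -0.34 for T cell, -0.93 for B and plasma cell, 0.057 for macrophage, -0.28 for interferon gamma, -0.88 for matrix and 0.60 for dermal papilla genes. With each spot weighted equally they were -1.25 for B and plasma cell and -0.48 for matrix genes. With all spots thinned to 1000 UMIs they were -0.46 for matrix and 0.010 for immediate early genes. For proliferation genes the region-standardised median was 0.21 and the median without regions 8 and 10 was 0.28.

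Regions with at least 20 spots of both arrays, 2 in the main clustering, numbered 0 at Leiden resolution 0.3 and with genes scaled within each array, and 1 at resolution 0.8 and with 1000 variable genes. The alopecia areata share of the region matched to region 1 was 0.495% at resolutions 0.3 and 0.8, 0.0% with 1000 variable genes, 1.07% with genes scaled within each array, 0.083% with all genes and 0.165% with spots of at least 500 UMIs, and its scarring alopecia share was 10.4% at resolution 0.8 and 16.8% with 1000 variable genes. The alopecia areata share of region 4 was 0.991% at resolutions 0.3 and 0.8 and with 1000 variable genes, 0.165% with genes scaled within each array and 6.11% with spots of at least 500 UMIs, and its scarring alopecia share was 5.42% at resolution 0.3, 5.78% with all genes and 5.01% with spots of at least 500 UMIs.

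In T cell spots of the scarring alopecia array, without standardising by region the log2 values were 2.03 for cytotoxic, 2.24 for B and plasma cell, 0.88 for interferon gamma, 1.71 for MHC class II and 1.299 for matrix genes, and on the alopecia areata array 1.33 for cytotoxic, 0.52 for interferon gamma, 1.05 for MHC class II, 0.071 for PPAR gamma and peroxisome and -0.047 for immediate early genes. With spots defined on all counts they were 0.52 for cytotoxic, 0.056 for B and plasma cell, 0.30 for interferon gamma, 0.90 for MHC class II, 0.58 for matrix and 0.28 for keratinocyte stress genes on the scarring alopecia array, and -0.093 for B and plasma cell, -0.003 for type I interferon and 0.89 for MHC class II genes on the alopecia areata array. With at least 2 T cell UMIs they were 0.14 for B and plasma cell genes on the scarring alopecia array, and 1.52 for cytotoxic, -0.094 for B and plasma cell and 0.86 for MHC class II genes on the alopecia areata array. At a thinning depth of 500 UMIs they were 0.70 for B and plasma cell, 0.25 for interferon gamma, 0.36 for MHC class II and 0.71 for haemoglobin genes on the scarring alopecia array, and 0.62 for MHC class II genes on the alopecia areata array. The shares of spots with a T cell UMI were 22.9% and 16.6% at 500 UMIs, 83.6% and 70.9% without thinning and 14.2% and 5.92% with at least 2 UMIs, each lower on the alopecia areata array.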

Other observations

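Transcripts of plasmacytoid dendritic cells, a source of type I interferon, differed between the arrays. The 10 genes were listed after some had been seen to lead region 5, so the direction of CLEC4C, SPIB and NIBAN3 is not independent evidence. CLEC4C was at 11.1 CPM on the scarring alopecia array and 1.12 CPM on the alopecia areata array (log2 ratio -3.25, -4.24 to -2.50), SPIB at 14.0 and 2.86 CPM and NIBAN3 at 10.9 and 2.16 CPM. LILRA4, not chosen from that region, had 72 and 3 UMIs (-3.83, -6.35 to -2.44), IL3RA stood at -0.77 and TCF4 at -0.53. SCT (-1.12) and PACSIN1 (-1.25) were lower too, MAP1A was level (-0.04) and PTCRA had 6 and 5 UMIs. In region 5 CLEC4C reached 42.7 CPM, SPIB 53.7 CPM, LILRA4 17.9 CPM and GZMB 53.1 CPM.

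The tests without region 5 or another single region, without regions 8 and 10, with all spots thinned, by leading marker list and of GZMB were chosen after the data had been seen. The first pattern is the lower level of 5 immune lists on the alopecia areata array. The T cell, B and plasma cell, interferon gamma, type I interferon and MHC class II medians averaged -0.85 (-0.93 to -0.77). Other immune lists ran from dendritic and Langerhans cell genes at -0.94 to cytotoxic genes at -0.24, macrophage genes at -0.19 and mast cell genes at 0.07. With every spot thinned to 1000 UMIs the mean of the 5 medians was -0.74 (-0.81 to -0.57). This argues against the greater weight of deep spots as the cause of the pattern in the mean. It does so less for type I interferon genes, whose median of -0.66 moved to -0.37 with spots thinned (11 of 14 genes). With each spot weighted equally that median was -0.32. Thinning leaves the expected make-up of each spot unchanged, so it cannot decide other effects of a difference in UMIs per spot. A different make-up by tissue cannot be told apart from other causes, since with spots set against spots of the same leading marker list the mean was -0.56 (-0.69 to -0.51), ranging from interferon gamma at -0.28 to B and plasma cell at -0.93, but 1445 of 2631 spots lay within 0.5 standard deviations of another list, and within regions 1 and 4 the mean was 0.55 (0.22 to 0.59). Without region 5 the mean was 0.15 (0.10 to 0.26), so the pattern may rest on that infiltrated part of the scarring alopecia array, although leaving out a rich region of 1 array is one-sided and leaving out region 7 instead moved the T cell median to -1.30. Disease, person and section stay open, since whether region 5 lies on diseased sections was not tested.

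The second pattern is the higher level of dermal papilla and proliferation genes on the alopecia areata array, with a mean of both medians of 1.05 (0.93 to 1.18). With every spot thinned to 1000 UMIs the proliferation median was 1.01 (0.63 to 1.17) on 10 of 11 genes. For these genes this argues against the weight of deep spots, but thinning again cannot decide other effects of depth. For dermal papilla genes the weight of deep spots stays open, because only 3 of 9 had enough UMIs after thinning (median 1.14, 0.24 to 1.84). The mean of both lists was then 1.07 (0.60 to 1.34). Without regions 8 and 10 the mean was 0.43 (0.32 to 0.67), so these regions could carry much of the pattern, but whether they carry all of it cannot be told apart from a remaining difference with an interval this wide, and singly the proliferation median was 0.92 without region 8 and 0.29 without region 10, and the dermal papilla median 1.17 and 1.28. Within regions 1 and 4 the proliferation median was 0.21, close to the 0.16 of all genes there, and the dermal papilla median was 0.73 on 4 genes. Alopecia type and the number of growing follicles in a section were not tested.

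The third pattern is GZMB on the scarring alopecia array, at 14.0 CPM there and 1.90 CPM on the alopecia areata array. Both cytotoxic lymphocytes and plasmacytoid dendritic cells can make granzyme B, and within regions GZMB was above expectation in spots with plasmacytoid UMIs (0.41 on the log2 scale, 0.02 to 0.80, in 257 spots) and in spots with UMIs of other cytotoxic genes (0.62, 0.11 to 1.09, in 101 spots). Of the 257 spots 158 had a UMI of TCF4, which many cell types express, and with the list without TCF4 the value was 0.88 (0.44 to 1.28, in 111 spots), where T cell genes were also above expectation (0.41). The difference between plasmacytoid and cytotoxic spots was -0.22 (-0.85 to 0.41), so the sources cannot be told apart from the counts of 98 and 40 GZMB UMIs. That difference used the list with TCF4. Without TCF4 the plasmacytoid value of 0.88 lay above the cytotoxic value of 0.62, with overlapping intervals, so the order of the sources depends on the list. Regions 7 and 5 had GZMB at 1.40 and 53.1 CPM and CLEC4C at 1.12 and 42.7 CPM, with smaller gaps in GZMA (19.3 and 21.5 CPM), NKG7 (7.85 and 8.81), CD8A (3.08 and 4.41), PRF1 (6.17 and 13.2) and GZMK (1.68 and 5.23), yet these regions lie on different arrays and CLEC4C was listed for leading region 5, so either cell type or both could contribute, as a hypothesis from the same data.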
